A study of Homo sapiens with 14 samples.

How the data were processed

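ATAC-seq peak lists of 14 human lung libraries were analysed. Per the labels, each reaction used 50000 cells and 30 min of transposition. Omni-ATAC-seq washes the cells in a detergent buffer before transposition, and Fast-ATAC-seq omits that step. Per the submitters' processing notes, the tools were FastQC, cutadapt, Bowtie 1.0.1, Picard 1.114 and MACS2 2.1.1.20160309, and the genome build was hg19. Whether insertion sites were shifted for Tn5, how duplicates were treated and which MACS2 options were set is not given in the sources used here. Peaks were called per library and not on pooled samples, since each library has its own deposited list. These details matter because fragment extension sets the narrowest peak and read depth sets how many weak peaks pass.

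Each deposited list gives a fold enrichment per peak, the authors' ratio of signal at the summit to the local background. The deposited p and q values are on the −log10 scale, as MACS2 writes them, and the lowest −log10 q in the autosomal lists was 1.30, which corresponds to a q of 0.0500. The deposited score column was not used, and the summit offset was used only for windows around summits. Fold and −log10 values are the authors' own and served only to rank or filter peaks within a list, apart from a test by ranks within regions open in all libraries that is given among the closing observations. No counts or depths were analysed, so depth per sample is unknown, and the precision it gives cannot be stated.

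Lists were restricted to the 22 autosomes, which left out 2.46% of peak rows. Several summits of an interval were collapsed to a single peak with their highest values. Consensus regions are the merge of all autosomal peaks of all 14 libraries, overlapping or adjoining (180793 regions, median width 323 bp). A library counts as open at a region when a peak of it overlaps by 1 bp or more. A region is specific to a group when it is open in every library of that group and in no library of the other. Where a share of all regions in a comparison is given, it covers every region open in any of its libraries, including those open in a single one. Specific regions must be open in every library of a group, so their shares can differ from it for that reason alone. Coordinates are 1-based hg19 positions. Jaccard indices were computed with bedtools 2.31.1, and the rest with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

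Groups came from the labels: 16HBE14o- Fast, 16HBE14o- Omni, NHBE, SAEC, ATII and LF. Airway means NHBE and SAEC together, and primary epithelium means these with ATII. The comparisons were Fast against Omni, NHBE against SAEC, ATII against airway, 16HBE14o- Omni against airway and LF against primary epithelium. Library-level values (peak number, median peak width and covered length) were compared by exact permutation tests, two-sided, with Benjamini-Hochberg adjustment over the 9 tests, which were added after the lists had been seen. Median fold enrichment was at first among these measures and was then left out, since the caller's values are comparable only within a list; no test passed the adjusted threshold with or without it. Similarity was tested with 100000 relabellings, one-sided. Regions of ATII against airway were tested by Fisher's exact test with Benjamini-Hochberg adjustment. The groups, main comparisons, named-region rule and first set of alternatives were fixed before the data were examined.

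Named regions follow a rule for a build without annotation: for each comparison and direction, the 10 specific regions with the highest mean within-library percentile of peak fold enrichment. The text prints the leading ones of each set of 10 and, where said, those open in fewer other libraries. A region of the major histocompatibility complex was left out, since inherited haplotypes differ there. The gene table used here belongs to GRCh38.p14 and the lists to hg19, so regions were not assigned to genes, exons or promoters. For the same reason the planned gene-list, marker, promoter and motif results were not run. Sex chromosomes were left out because the primary cells come from human donors.

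Alternatives were a stricter threshold (−log10 q of 5 or more), lists limited to the 19238 strongest peaks by −log10 p, other definitions of an open region, other pooling of groups, replicate numbers as a block, and leaving out each library. Peak names in the ATII and LF lists follow a different pattern from the others. If this marks a processing batch, batch and cell type cannot be told apart, since no batch holds both ATII and airway libraries, and no within-batch value can be had.

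The region step was tested on simulated data of 20000 regions with 200 planted specific regions per direction. Planted regions met the definition of a specific region, so their recovery checked the code alone and not the power to find real differences. For ATII against airway, 2 other calls were made in the ATII direction where 4.19 were expected and 17 in the airway direction where 25.2 were expected. For NHBE against SAEC, 210 other calls were made in the NHBE direction where 232 were expected. In the SAEC direction 216 were made where 195 were expected. Presence was drawn independently for each library at its own rate, so these calls depend on list length as well as group size. Real lists share regions, so the simulated numbers do not estimate the chance calls in them.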

Results

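Open chromatin was profiled by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into accessible DNA, in 14 libraries from human lung cells. The cells were bronchial/tracheal epithelial cells (NHBE, 2 libraries), small airway epithelial cells (SAEC, 4 libraries), alveolar type II pneumocytes (ATII, 3 libraries), lung fibroblasts (LF, 1 library) and the immortalized bronchial epithelial line 16HBE14o- (4 libraries). Type II pneumocytes are the surfactant-secreting cells of the alveolus. The line was assayed with Fast-ATAC-seq (2 libraries) and with Omni-ATAC-seq (2 libraries), while the primary cells were assayed with Omni-ATAC-seq alone. NHBE and SAEC were cultured, and ATII cells went into the reaction directly after sorting. Read depth is unknown, since the analysed files hold peaks and no read counts, and no interval that needs depth is given.

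The number of autosomal peaks per library ranged from 19238 in ATII replicate 2-1 to 111792 in SAEC replicate 1-1. Group means were 26088.5 ± 2347 (SD, n = 2) for 16HBE14o- Fast, 42564 ± 1223 (SD, n = 2) for 16HBE14o- Omni, 60742.5 ± 2809 (SD, n = 2) for NHBE, 75936.5 ± 28129 (SD, n = 4) for SAEC and 32276 ± 14529 (SD, n = 3) for ATII. The LF library had 69806 peaks and stands without a replicate throughout. Merging the peaks of all libraries gave 180793 regions. Of these, 8466 (4.68%) were open in all 14 libraries, with a median width of 1137 bp, and 71252 (39.4%) were open in 1 library, with a median width of 197 bp. The number open in all was 4712 at −log10 q of 5 or more, 3253 in lists of equal length and 1780 where peaks had to cover 50% of a region, an alternative chosen after seeing the data.

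**Figure D1:**
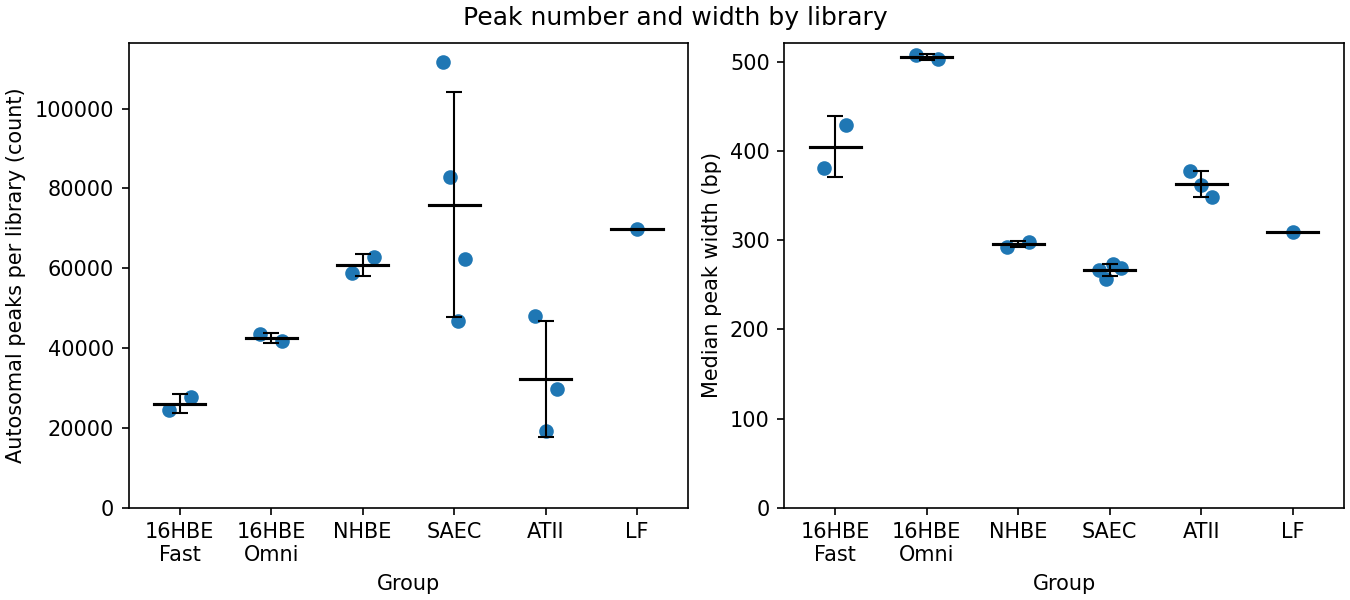
Number of autosomal peaks per library (left) and median peak width in bp (right) by group; points are libraries, horizontal lines group means and bars 1 SD, with no bar for the LF library. The 3 ATII libraries have median widths from 349 to 378 bp, above the 257 to 298 bp of the 6 NHBE and SAEC libraries.

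Libraries of a cell type resembled each other more than libraries of other types. The base-pair Jaccard index, the length shared by a pair of peak lists divided by the length covered by either, averaged 0.472 ± 0.0880 (SD, 16 pairs) within a cell type and 0.300 ± 0.0707 (SD, 75 pairs) between types. The difference of 0.172 had p = 1e-05 in a one-sided permutation test with 100000 relabellings, the smallest p they can give. Each of the 13 libraries with another library of its type was closest to one of that type. Outside ATII, that closest list always shared both the group and the first number of the sample title. With that list set aside, SAEC replicates 1-1, 2-1 and 2-2 were closest to an NHBE list, at 0.454, 0.472 and 0.498. SAEC replicate 1-2 was then closest to SAEC replicate 2-2, at 0.492. The Omni libraries of 16HBE14o- were the closest pair, at 0.693. NHBE and SAEC lists overlapped each other (0.473 ± 0.0205, SD, 8 pairs) about as much as SAEC lists overlapped among themselves (0.467 ± 0.0691, SD, 6 pairs). In full lists, ATII overlapped the airway lists of NHBE and SAEC at 0.251 ± 0.0371 (SD, 18 pairs), the LF list at 0.242 ± 0.0381 (SD, 3 pairs) and the lists of 16HBE14o- at 0.290 ± 0.0310 (SD, 12 pairs). The order of airway and LF depended on list length: in equal-length lists the values were 0.251 ± 0.0260 for airway, 0.310 ± 0.0174 for LF and 0.331 ± 0.0195 for the line (SD, the same pairs). There the pairs of ATII and LF ranged from 0.291 to 0.325 and those of ATII and airway from 0.204 to 0.277; this difference was not tested. The labels do not say whether replicates came from separate cultures or donors, so p-values here measure only the spread between these libraries, which may be technical.

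**Figure D2:**
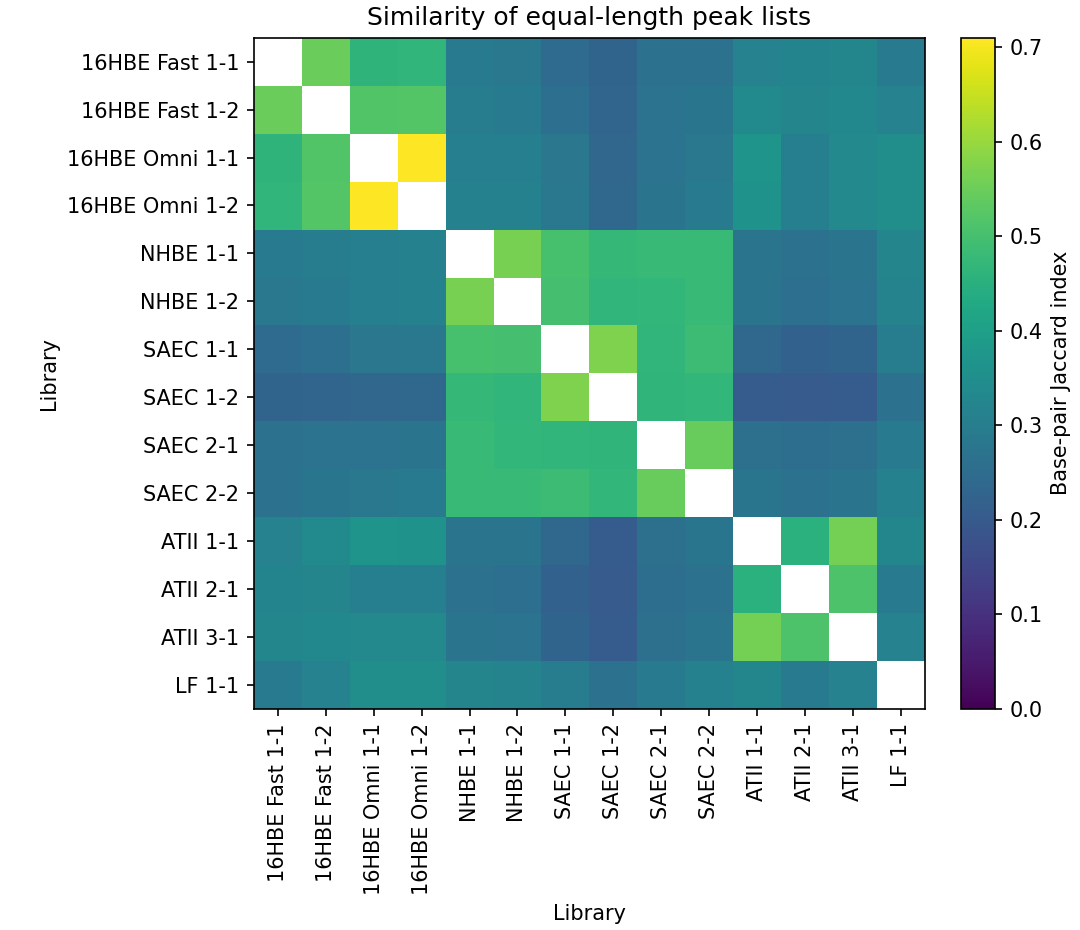
Base-pair Jaccard index of each pair of libraries, computed on the 19238 strongest peaks of each library; rows and columns are libraries, colour is the index and the diagonal is left blank. Blocks of higher values mark 16HBE14o-, ATII and airway lists, with NHBE and SAEC in a common block (mean 0.481 between them). The mean was 0.520 within cell types and 0.307 between them.

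In 16HBE14o- cells, Omni-ATAC-seq yielded many more peaks and specific regions than Fast-ATAC-seq. The comparison asks how the protocol, which differs in its lysis step and detergents, changes the peaks of a single line. Of 51766 regions open in any of the 4 libraries, 18556 were open in all, 9940 (19.2%) were open in both Omni libraries and neither Fast library, and 108 (0.209%) showed the opposite pattern. The Omni-specific regions ranked highest by fold enrichment within their libraries lay on chromosome 1 at 206137998 to 206138424, on chromosome 16 at 16326234 to 16326662 and on chromosome 1 at 1677510 to 1678203, with mean percentiles of 99.99, 99.97 and 99.94 (n = 2). The leading Fast-specific regions, on chromosome 7 at 133390103 to 133390609 and on chromosome 13 at 65486206 to 65486714, had percentiles of 79.3 ± 18.9 and 79.3 ± 6.49 (SD, n = 2). These Fast-specific regions were open in 8 and 3 of the 14 libraries, and the Omni-specific ones named above in 11, 11 and 10. Each was thus also open in primary cells, which were assayed with Omni-ATAC-seq alone. Percentiles here are ranks within lists of different length and are not compared between groups. Of the Omni-specific regions, 48.8% were open in LF, 36.2% in both NHBE libraries and 8.33% in all ATII libraries, against 55.2%, 48.5% and 23.9% of all regions in this comparison. With 2 libraries on each side no test of this difference was made. In lists of the same length the counts lay close together, with 1951 Omni-specific and 1569 Fast-specific regions, and leaving out single libraries gave 212 to 2384 Fast-specific and 12015 to 15712 Omni-specific regions.

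Large and small airway epithelium were compared in 6 libraries, and the number of regions that set them apart depended on how libraries were counted. Of 131313 regions open in any of the 6 libraries, 31535 were open in all, 620 (0.472%) were open in both NHBE libraries and no SAEC library, and 1934 (1.47%) in all SAEC libraries and no NHBE library. The SAEC-specific count was 17498 with the title numbers as a replicate block, and counting libraries with the same first number once gave 2595 NHBE-specific and 5362 SAEC-specific regions. In the latter count a first number was open only where all its libraries were open. Such regions may therefore have a peak in some library of the other group, a looser rule that raises the counts. The leading SAEC-specific regions lay on chromosome 7 at 80820252 to 80820626, on chromosome 1 at 114084804 to 114085216 and on chromosome 5 at 79812637 to 79813136, with mean percentiles of 96.5 ± 3.17, 96.4 ± 2.01 and 95.5 ± 2.22 (SD, n = 4). The leading NHBE-specific regions, on chromosome 12 at 8542612 to 8543501 and on chromosome 20 at 43716662 to 43717314, had percentiles of 87.0 ± 7.80 and 86.7 ± 12.1 (SD, n = 2). SAEC-specific regions were open in LF in 34.2% of cases, near the 34.9% of all regions in this comparison, while 17.9% of NHBE-specific regions were. Median peak width was 295.5 bp in NHBE and 266.5 bp in SAEC (exact permutation test, two-sided, p = 0.0667, the smallest p that 15 splits allow; adjusted p = 0.150 over 9 tests). The direction of the imbalance depended on list length: lists of equal length gave 862 NHBE-specific and 574 SAEC-specific regions. Single libraries moved the counts too: 1661 NHBE-specific regions without SAEC replicate 1-1, 5349 SAEC-specific regions without SAEC replicate 2-1, and 5401 and 3400 NHBE-specific with 3551 and 3745 SAEC-specific regions without NHBE replicates 1-1 and 1-2.

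Alveolar type II cells and cultured airway epithelium each had regions that no library of the other opened. Of 149548 regions open in any of the 9 libraries, 11299 were open in all, 1636 (1.09%) were open in all 3 ATII libraries and none of the 6 NHBE and SAEC libraries, and 13612 (9.10%) in all airway libraries and no ATII library. The leading ATII-specific regions lay on chromosome 7 at 34059062 to 34059531, on chromosome 18 at 26582882 to 26583563, on chromosome 4 at 23891445 to 23892144 and on chromosome 1 at 224493717 to 224494298. Their mean percentiles were 96.1 ± 3.24, 95.2 ± 6.28, 93.7 ± 4.64 and 92.9 ± 10.5 (SD, n = 3), and each was open in 3 of the 14 libraries, those of ATII. The leading airway-specific regions lay on chromosome 15 at 43137805 to 43138145, on chromosome 12 at 18843560 to 18843968 and on chromosome 11 at 14358527 to 14359118, with percentiles of 99.9 ± 0.0933, 99.9 ± 0.150 and 99.8 ± 0.147 (SD, n = 6). Those on chromosomes 12 and 11 were open in 11 of the 14 libraries, so that they were shared with the line and the fibroblasts, whereas regions on chromosome 18 at 28483497 to 28483871 and on chromosome 7 at 55766656 to 55767358 were open in the 6 airway libraries alone. Airway-specific regions were open in LF in 47.9% of cases and in both Omni libraries of 16HBE14o- in 30.4%, against 31.6% and 21.3% of all regions in this comparison. ATII-specific regions were open in LF in 10.3% and in both Omni libraries in 6.60% of cases. All regions here include those open in a single library, while airway-specific regions were open in every airway library. The higher airway shares therefore do not by themselves show a particular sharing with LF or the line. In equal-length lists 18.4% of ATII-specific and 36.3% of airway-specific regions were open in LF.

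ATII peaks had a larger median width than airway peaks in full lists, with a mean of library medians of 363 ± 14.5 bp (SD, n = 3) against 276 ± 16.0 bp (SD, n = 6). This exact permutation test, two-sided, gave p = 0.0119, the smallest that 84 splits allow, and an adjusted p of 0.107 over 9 tests, which misses the threshold of 0.05. In full lists 3 of 3 ATII libraries lay above every airway library. In equal-length lists the difference was 55.3 bp (exact permutation test, two-sided, p = 0.440), and ATII replicate 2-1, at 362 bp, lay below every airway library. The ATII lists held 32276 peaks on average and the airway lists 70872 ± 23192 (SD, n = 6; exact permutation test, two-sided, p = 0.0595, adjusted p = 0.150). Fisher's exact test, two-sided, on each of 138249 regions gave no region past a Benjamini-Hochberg adjusted 0.05 (smallest adjusted p = 0.108), and 22615 regions with an unadjusted p under 0.05, of which 20523 were open more often in airway and 2092 in ATII. Every specific region had an unadjusted p of 0.0119 in Fisher's exact test, the smallest that 3 against 6 libraries allow. The lack of passing regions therefore reflects the number of libraries together with how many regions reached that p, and says nothing about single regions. Fresh sorting against culture went with the cell type and was not separable from it. With equal-length lists the counts were 3532 ATII-specific and 3874 airway-specific regions, and without ATII replicate 2-1, the shortest list, 5318 regions were ATII-specific.

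The 16HBE14o- line and primary airway cells were separated by 16695 specific regions in both directions, where ATII and airway were separated by 15248, with 2 libraries of the line and 3 of ATII. Of 141263 regions open in any of the 2 Omni libraries and 6 airway libraries, 18480 were open in all, 5182 (3.67%) were specific to the line and 11513 (8.15%) to the airway libraries. The leading regions of the line lay on chromosome 21 at 37640063 to 37640685, on chromosome 11 at 63348595 to 63349309 and on chromosome 15 at 30762934 to 30763723, with mean percentiles of 99.9 ± 0.0725, 99.8 ± 0.0105 and 99.7 ± 0.317 (SD, n = 2). The leading airway region, on chromosome 15 at 43137805 to 43138145, was also the leading airway region against ATII, and the next lay on chromosome 11 at 43398126 to 43398505 (99.9 ± 0.192, SD, n = 6). Regions specific to the line were open in both Fast libraries in 24.4% of cases and in LF in 21.5%, and 13.3% were open in any ATII library, against 13.4%, 33.7% and 23.7% of all regions in this comparison. Airway regions absent from the Omni libraries were open in LF in 41.5% of cases and in both Fast libraries in 0.130%, against the same backgrounds of 33.7% and 13.4%. These backgrounds include regions open in a single library, so shares above them do not by themselves show a particular sharing. Median peak width was 505.5 ± 3.54 bp (SD, n = 2) in the line and 276 bp in airway (exact permutation test, two-sided, p = 0.0357, the smallest that 28 splits allow; adjusted p = 0.150 over 9 tests). Equal-length lists turned the imbalance round, with 4918 line-specific and 3195 airway-specific regions. The line-specific count was 7915 without Omni replicate 1-2 and 1262 with the Fast libraries added.

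**Figure D3:**
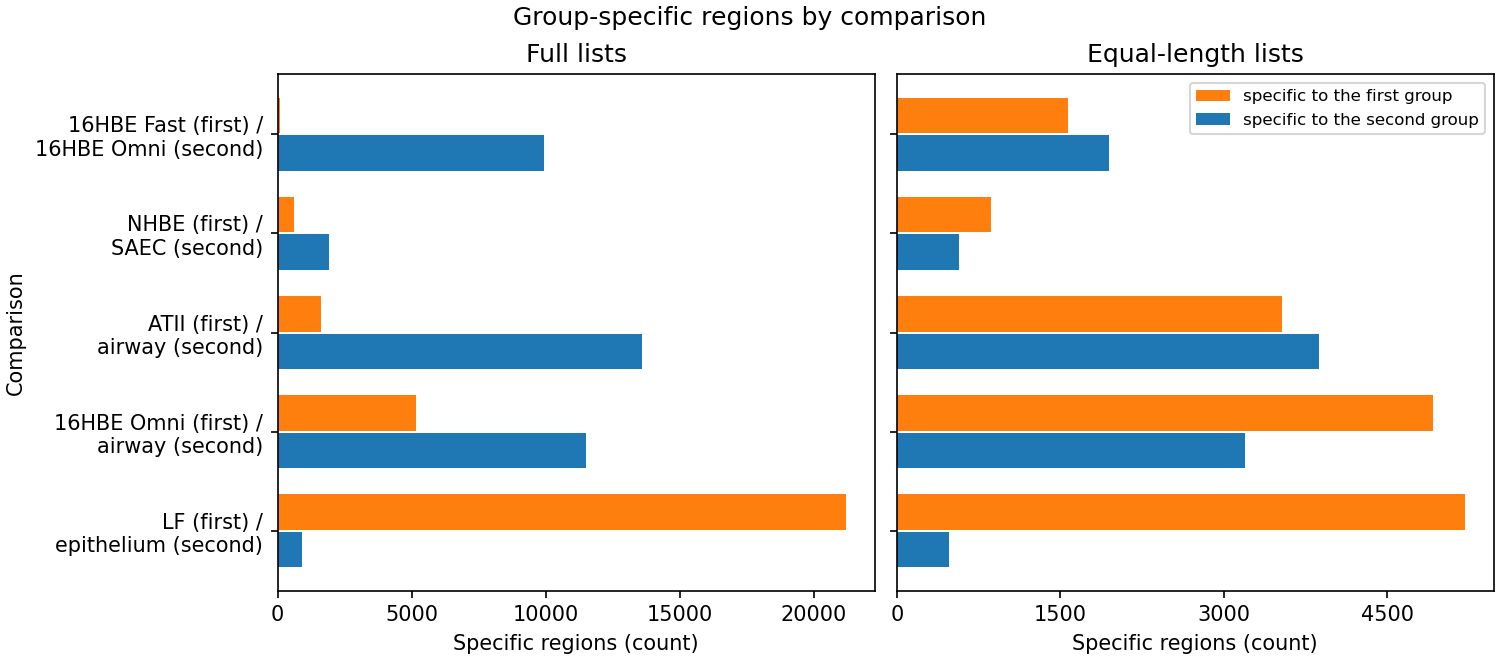
Regions open in every library of a group and in no library of the other, for the 5 comparisons, from full lists (left) and from lists of 19238 peaks each (right); bars are counts and have no error bars. In full lists 108 regions are specific to Fast and 9940 to Omni, against 1569 and 1951 in equal-length lists.

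Fibroblasts, the mesenchymal cells of the set, had many regions seen in no primary epithelial library, a count that only 1 library had to meet. Of 170754 regions open in LF or any of the 9 primary epithelial libraries, 10380 were open in all 10 of them, 21206 (12.4%) in LF alone and 919 (0.538%) in all 9 epithelial libraries and not in LF. The leading epithelial regions lay on chromosome 15 at 46212018 to 46212419, on chromosome 1 at 51086372 to 51087023 and on chromosome 3 at 185255172 to 185255759, with mean percentiles of 95.7 ± 3.46, 95.2 ± 2.57 and 94.8 ± 8.24 (SD, n = 9). Regions on chromosome 5 at 140383526 to 140384207 and at 78469379 to 78469870 were open in the 9 primary epithelial libraries and not in the line. The leading LF regions lay on chromosome 1 at 144691878 to 144692156, on chromosome 7 at 55393127 to 55393444 and on chromosome 4 at 114289231 to 114289626, at percentiles of 99.999, 99.94 and 99.83. Of the regions open in all primary epithelium and closed in LF, 56.5% were open in both Omni libraries of 16HBE14o-, against 19.1% of all regions in this comparison, while 4.15% of LF-specific regions were. All regions include those open in a single library, so regions open in all 9 epithelial libraries may be open elsewhere more often in any case. LF had 1 library, so no test between the groups was made and its regions include any chance calls of that library. Equal-length lists gave 5217 LF-specific and 482 epithelial regions, the 6 airway libraries alone gave 9940 epithelial regions, and leaving out ATII replicate 2-1 gave 1567.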

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

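The checks in this part were chosen after the lists were seen. Of 32 combinations of group and library-level measure, 3 had a library far from the others, and chance alone gives about 1 in 20. SAEC replicate 1-1 had 16.7% of its open regions in no other library, where the next SAEC library had 6.03% and the next of all 6 airway libraries 6.53%. The gap was 0.896 of the SAEC range and 0.800 of the airway range. This library also had the longest list, 111792 peaks. SAEC replicate 1-2 had more than 1 summit in 11.5% of its peaks, where the next SAEC library had 13.6%, a gap of 0.867 of the range.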

How the results depend on the processing

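The similarity difference kept its direction and its side of the threshold under every alternative run: it was 0.159 at the stricter threshold, 0.214 in equal-length lists, 0.234 by share of overlapped peaks, and 0.162 to 0.183 when single libraries were left out. Counts of specific regions moved far more. For these results the alternatives were fixed before the data were examined, except that peaks must cover 50% of a region. Library-level tests, chromosome shares, region classes, shares open in LF and the alternatives for named regions were chosen after seeing the data. Of the 10 named regions per direction, 7 Fast-specific ones stayed specific at the stricter threshold. In equal-length lists 7 NHBE-specific, 8 SAEC-specific and 9 epithelial ones did. All 10 stayed specific in every other case, which their choice by high rank favours. No library-level test passed after adjustment under any alternative, and in designs this small that says nothing about stability.

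At −log10 q of 5 or more, counts fell to 549 ATII-specific (against airway), 18 Fast-specific, 400 epithelial (against LF) and 278 NHBE-specific regions, while 13532 Omni-specific regions (against Fast) and 5328 line-specific regions (against airway) were counted; the cause was not tested. Equal-length lists gave 3195 airway-specific regions against the line, 3532 ATII-specific and 3874 airway-specific, 1569 Fast-specific and 1951 Omni-specific, 5217 LF-specific and 482 epithelial, and 574 SAEC-specific regions. Fixed windows around summits moved the Fast-specific count to 313. The demand for 50% coverage gave 9954 line-specific and 5406 airway-specific, 6290 airway-specific against ATII, 247 epithelial and 961 NHBE-specific regions; the cause was not tested. An overlap of 50% of the shorter of peak and region changed nothing by construction, since a peak lies wholly inside its merged region.

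Other groupings use fewer or other samples. Against NHBE alone, ATII had 2708 specific regions and NHBE 23902, and the Omni libraries had 9893 and NHBE 20360. All 4 libraries of the line gave 1262 line-specific regions, and the 6 airway libraries alone gave 9940 against LF. Counting libraries with the same first title number once gave 8923 line-specific, 382 Fast-specific, 17749 Omni-specific, 2595 NHBE-specific and 5362 SAEC-specific regions. A first number was open there only where all its libraries were open, so a peak in some library of the other group was allowed.

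Same-numbered libraries did not deviate together (correlation −0.00197 for Fast and Omni, 0.00104 for NHBE and SAEC, −0.110 for ATII and SAEC, 2 pairs each), so the numbers were not taken to pair libraries across groups, although SAEC lists grouped by first number. With the replicate block, SAEC-specific regions rose to 17498, where 2 SAEC libraries drop out by construction, and no other count moved by over 1.5 times.

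Leaving out single libraries gave 5223 to 7915 line-specific and 11522 to 14618 airway-specific, 1651 to 5318 ATII-specific and 13623 to 17350 airway-specific, 212 to 2384 Fast-specific and 12015 to 15712 Omni-specific, 21232 to 24661 LF-specific and 919 to 1567 epithelial, and 648 to 5401 NHBE-specific and 2010 to 5349 SAEC-specific regions. Counts rise here by construction, since fewer libraries must meet the condition. Gene-list, promoter and motif alternatives were not run. Depth is unknown, so its effect on list length was not measured.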

Other observations

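All tests in this part were chosen after the lists were seen, except the count of specific regions over splits of the ATII and airway libraries, which was planned; the predictions for neighbouring bins were written before each of those tests was run, and the version with chromosome means removed was added after the other had been seen.

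Airway cells and fibroblasts shared a set of regions in which the ATII and 16HBE14o- lists had no peak. In all, 3167 regions were open in all 6 airway libraries and LF and in no ATII or 16HBE14o- library, against 112 open in the 3 ATII libraries and LF alone, 348 in ATII and airway alone, 613 in airway and the 4 libraries of the line alone, 238 in the line and LF alone, and 17 in ATII and the line alone. The contrast was smaller in equal-length lists, where the counts were 632 for airway and LF, 126 for ATII and LF, 130 for ATII and airway, 361 for airway and the line, 241 for the line and LF and 383 for ATII and the line. Airway and LF had the longest full lists on average, and the classes demand different numbers of open libraries. The counts are therefore no ranking of how alike the cell types are. Where peaks had to cover 50% of a region, airway and LF shared 1292 regions, ATII and LF 55 and ATII and airway 81. Airway and the line then shared 216, the line and LF 235 and ATII and the line 21. At −log10 q of 5 or more, airway and LF shared 2345 regions, ATII and LF 40 and ATII and airway 127. There airway and the line shared 368, the line and LF 151 and ATII and the line 11. Without ATII replicate 2-1 the counts were 3176 for airway and LF, 332 for ATII and LF, 674 for ATII and airway and 40 for ATII and the line. The line and LF shared 400 regions without Fast replicate 1-1 and 363 without SAEC replicate 1-1, and ATII and the line 31 without Fast replicate 1-1. Without LF, whose regions then no longer count against a class, ATII and airway shared 755, airway and the line 2000, and ATII and the line 31. ATII alone held 1374 regions, airway 5287, the line 868 and LF 19693. These counts moved with the processing. The ATII count was 407 at −log10 q of 5 or more, 1840 in equal-length lists and 4576 without ATII replicate 2-1. The airway count was 1724 in equal-length lists, 3088 with 50% coverage and 8454 without LF. The LF count was 4432 in equal-length lists. The count for the line was 530 at the stricter threshold, 1520 in equal-length lists and 1512 without Fast replicate 1-1. Regions of the ATII, airway, line and LF classes lay closer together along the genome than random draws. Another region of the same class lay within 10 kb for 4.22% of ATII-only regions, where the mean of 1000 random draws of consensus regions was 1.47%. The values were 9.55% against 5.49% for airway, 6.22% against 0.934% for the line and 30.3% against 18.8% for LF, and each permutation test by random draws gave p = 0.000999, the smallest these draws can give. The LF value rests on a single library. For SAEC alone the share was 1.98% against 0.880% (permutation by random draws, p = 0.0190), and for NHBE alone 1.01% against 0.434% (p = 0.224), which did not pass. The draws were not matched for region width or for the number of libraries open, and neighbouring regions are not independent. Their p-values therefore describe the lists only and do not tie the closeness to the cell types.

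Specific regions were also counted in windows of 500 kb and set against a hypergeometric expectation with Benjamini-Hochberg adjustment; neighbouring regions are not independent, so these p-values describe the lists only. For ATII against airway, 2 windows passed for ATII: chromosome 13 from 113000001 to 113500000 with 9 ATII-specific of 52 regions (0.569 expected) and chromosome 2 from 6500001 to 7000000 with 5 of 14 (0.153 expected). For airway 6 windows passed, led by chromosome 12 from 107500001 to 108000000 with 15 of 39 (3.55 expected). For the line against airway 28 windows passed, led by chromosome 12 from 54000001 to 54500000 with 13 of 39 (1.43 expected) and chromosome 20 from 55500001 to 56000000 with 12 of 42 (1.54 expected). Windows also passed between protocols within the line. There 14 passed for Omni against Fast, led by chromosome 19 from 11000001 to 11500000 with 20 of 32 (6.14 expected). Passing windows are thus not particular to differences of cell type. For LF against primary epithelium, where a single library decides what counts as LF-specific, 141 windows passed and held 9.15% of LF-specific regions, led by chromosome 4 from 16500001 to 17000000 with 21 of 28 (3.48 expected).

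Whether chance assignment of libraries could give such counts was examined by counting specific regions in both directions for every other split of the same libraries. For ATII against airway the real split gave 15248 regions and the highest other split 2658. The real value was reached by 1 of 84 splits, a share under 0.05 if each library counts as independent. Such a share makes chance assignment less likely and does not exclude it. With libraries of a group that share a first title number as 1 unit, the real split gave 16034 and the highest other 990, and 1 of 10 splits reached the real value, too few splits for a share under 0.05. Such a unit counted as open only where all its libraries were open. For the line against airway the real split gave 16695 and the highest other 9641. Here 1 of 28 splits reached the real value, again a share under 0.05 only for independent libraries. With first numbers as units the values were 21978 and 21481, and 1 of 4 splits reached the real value, again too few for a share under 0.05. For NHBE against SAEC the real split gave 2554 and the highest other 11505, and 3 of 15 splits reached the real value; 15 splits are too few for a share under 0.05. The highest split parted SAEC replicates 1-1 and 1-2 from the rest, and in equal-length lists the highest parted SAEC replicates 2-1 and 2-2 from the rest (1531 regions against 1436 for the real split), which points to a structure that follows the first number of the sample titles. SAEC lists with the same first number had an equal-length Jaccard index of 0.559 ± 0.0191 (SD, 2 pairs), those with different first numbers 0.472 ± 0.00931 (SD, 4 pairs), and NHBE with SAEC lists 0.481 ± 0.0134 (SD, 8 pairs).

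The unequal numbers of specific regions were weighed against list length. The ratio of airway-specific to ATII-specific regions was 8.32 in full lists and 1.10 in equal-length lists, and that of Omni-specific to Fast-specific regions 92.0 and 1.24. With 2 libraries on each side, cutting all lists to the same length draws the Omni and Fast counts together whatever the cause. The ratio of 1.24 therefore cannot tell list length from other causes. At −log10 q of 5 or more, 18 Fast-specific and 13532 Omni-specific regions were counted. That threshold kept 84.7% and 84.9% of the Omni peaks and 52.9% and 63.6% of the Fast peaks. Leaving out weaker peaks thus did not reduce the imbalance, which argues against weak peaks in the Omni lists as its source. An airway-specific region must be open in 6 libraries and an ATII-specific one in 3, so groups without a difference need not give 1. There the fall from 8.32 to 1.10 shows that the ratio depended on list length. Whether list length was the whole cause cannot be told. Whether list length itself reflects depth, library quality or the cells cannot be read from peak lists, and the biological difference between cell types stays open and untested.

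The wider peaks of ATII and of the Omni libraries were weighed against the narrowest peak the caller allowed and the make-up of the lists. Median width divided by each library's narrowest peak stayed higher in every ATII library (2.55 ± 0.181, SD, n = 3) than in every airway library (2.05 ± 0.162, SD, n = 6; exact permutation p = 0.0119) and in both Omni libraries (2.53, n = 2; exact permutation p = 0.0357), which argues against the narrowest allowed peak as the whole cause. Within the regions open in all 14 libraries the Omni libraries were still wider (920 bp, n = 2, against 654 bp, n = 6; exact permutation p = 0.0357), which argues against list make-up for the Omni libraries. The Fast libraries of the same line, at 612 and 722 bp, lay within the airway range of 581 to 751 bp there, so this does not extend to the line as a whole. In equal-length lists the ATII difference in width was 55.3 bp (exact permutation p = 0.440). For ATII the medians within regions open in all were 690 ± 148 bp (SD, n = 3; exact permutation p = 0.714), a spread larger than the full-list difference of 86.8 bp, so list make-up and a difference of the cells cannot be told apart there. Depth was not testable, and the cell type, fresh sorting and a processing batch stay open.

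Peaks of 16HBE14o- were spread unevenly over chromosomes relative to the 9 primary epithelial libraries. In an exact permutation test over 715 splits, adjusted over 22 chromosomes, 7 chromosomes passed: the share of peaks was lower in the line on chromosomes 3 (5.73% against 6.83%), 11 (4.92% against 5.35%) and 18 (1.86% against 2.27%) and higher on chromosomes 6 (6.78% against 6.25%), 7 (5.50% against 5.04%), 20 (3.03% against 2.64%) and 1 (10.3% against 9.93%), with adjusted p from 0.00615 to 0.0440. In equal-length lists 6 of the 7 passed the same way, which argues against list length as the cause. Of 100 splits drawn from the 715, 2 gave as many chromosomes, the real one included. This share is under 0.05 only if each library counts as independent. With the line as 1 unit there are 7 splits, too few for a share under 0.05. The highest other split, with both Omni libraries and ATII replicates 1-1 and 2-1 on a side, gave 10 chromosomes, so chromosome shares also follow some other structure of these libraries.

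A candidate explanation for the chromosome shares is copy number in this line. If copy number acts over large segments, neighbouring bins of 10 Mb should shift together, and the log2 ratios of line to airway peak shares in neighbouring bins had a correlation of 0.446 across 238 pairs of bins, which are not independent replicates, against 0.137 for ATII and 0.0521 for LF. Shifts of whole chromosomes raise this value by themselves. With the mean of each chromosome removed it was 0.321 for the line, −0.0316 for ATII and −0.113 for LF, differences of 0.352 (jackknife SE 0.117) and 0.434 (jackknife SE 0.107), although the line has 4 libraries and LF 1, and averaging over fewer libraries lowers a correlation. For whole chromosomes the evidence was mixed: within regions open in all 14 libraries, ranks of −log10 p shifted the same way on 6 of the 7 chromosomes and passed the test on 4 of them, while chromosome 1 shifted the opposite way by −0.0811 percentile points and did not pass. Segments of changed copy number are therefore consistent with the bins and remain a hypothesis, since regional differences of chromatin in the line were not tested, while whole-chromosome changes cannot be told apart from other causes, because chromosomes that passed no test of peak shares, such as 2, 5 and 14, shifted in rank as well.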
